A study of Mus musculus with 5 samples.

How the data were processed

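HSF1, the transcription factor that drives the heat shock response, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary cortical neurons of Swiss-Webster mouse embryos at embryonic day 16. The neurons were kept in culture until day 13. NMDA, an agonist of one class of glutamate receptors, was given at 50 µM for 10 min and followed by 20 min in drug-free medium, per the labels' protocols. The 5 samples were 2 control ChIP libraries, 2 NMDA ChIP libraries and 1 input library, which is sheared chromatin without immunoprecipitation. The input came from neurons without NMDA, so the NMDA libraries had no input of their own condition. The labels call the ChIP libraries of a condition biological replicates.

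The authors deposited 2 peak lists, 1 per condition, and these were the data used. FastQC, Trimmomatic, BWA, SAMtools and MACS2 are named, without versions, together with the builds mm10 and GRCm38.p6, per the submitters' processing notes. How the replicates were merged into a list is not given in the sources used here. The list names call the peaks replicated and the input single. Each list was taken as belonging to the condition in its name. Each peak of the deposited lists has a score from 10 to 1000. The deposited fold enrichment is a ratio of the ChIP signal at the summit over a background value. How far the input at a peak sets that background is not given in the sources used here. The authors' peak p and q are given as −log10 values, and the distance from the peak start to the summit completes the entry. The lowest −log10 p was 2.06 in the control list and 2.03 in the NMDA list. The lowest −log10 q was 0.0446 and 0.0802. The lists therefore hold peaks above a q of 0.05. The 3316 control peaks had 383 distinct fold values and the 3646 NMDA peaks had 467. Fold values were used mainly to describe, rank and filter peaks within a list, because each list is scaled by its own libraries. Where fold counts or medians of the 2 lists are set side by side, that difference in scale remains. Read counts were not analysed here, so the depth of the libraries and the precision it gives are unknown.

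Gene positions came from a table of the GRCm38.p6 annotation with 21627 protein-coding genes on chromosomes 1 to 19 and X, and 49550 genes of all kinds. The table gives the start and end of a gene but neither strand nor exons. The analysis had been designed around transcription starts. It was run on gene ends instead, meaning that a peak was assigned to a gene when its summit lay within 1000 bp of either annotated end. A promoter and a 3′ end cannot be told apart in this way, and exon, intron and untranslated region are not stated for any peak. Genome sequence was not used here. The planned searches for heat shock elements and for repeat content were therefore not run, and assembly gaps were not avoided in random placements.

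Peaks were called shared when they overlapped a peak of the other list by at least 1 bp. The number shared was set against 1000 placements of the other list at random positions of the same chromosomes, between the outermost annotated genes or peaks (one-sided permutation p, whose smallest value is 0.001). Peaks on the mitochondrial genome and on unplaced sequences stayed in place. The median fold of shared and unshared peaks was compared by a two-sided permutation test with 100000 resamples. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Unshared control and unshared NMDA peaks were compared by a two-sided Fisher's exact test. The 11 gene lists were tested in both peak lists by two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 22 tests. Genes with a peak in 1 list were compared by an exact McNemar test, which was added after the data were examined. Peaks and genes are not replicates, so all these tests compare the 2 lists and not the conditions.

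The gene lists covered heat shock and chaperone genes, immediate early genes, glutamate receptor and synaptic genes, proteasome genes, cytosolic ribosomal protein genes, and topoisomerase, break repair and cohesin genes. Marker lists of neurons, astrocytes, microglia and the oligodendrocyte lineage were included, and olfactory receptor genes served as a negative control. Lists, most tests and most alternatives were fixed before the data were examined, apart from the change from transcription starts to gene ends. The test of chromosome X and the test of the median fold of chaperone gene-end peaks were not among the planned tests. Named items were the 10 peaks of highest fold in each list, the 10 unshared peaks of highest fold in each list, and the chaperone and immediate early genes with a gene-end peak, up to 15 per list by fold. The value of 1 chaperone gene is not reported here, and the gene stays in the counts. A peak took the name of the protein-coding gene with an end within 5000 bp of its summit and was otherwise given by position, with the gene it lies inside where there is one. Top2b, Cwc22, Npas4, Fosb, Hsf1 and the sites on chromosome X are described in further detail because of their values. Alternatives covered the overlap rule, the peak threshold, the window, the random placement, the background and the chromosomes included.

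The procedures were tested on simulated data. Over 21627 genes, the gene list test called 0% of 50 runs with no planted gene, 88% with 3 planted genes and 100% with 6. Simulated peaks lay at random positions, which puts 3.01% of them at gene ends, against 14.8% in the control list and 10.0% in the NMDA list. These rates may therefore not hold for the real lists, where more genes have a gene-end peak. Over 3316 peaks, the overlap test called 5% of 20 runs on random lists and 100% with 20 planted overlaps. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.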

Results

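HSF1 ChIP-seq was analysed in mouse primary cortical neurons without treatment (2 libraries) and after NMDA (2 libraries), with 1 input library from untreated neurons. The series concerns HSF1 and the engagement of topoisomerase IIβ, the DNA-cleaving enzyme encoded by Top2b, in the neuronal genome. Results are 1 peak list per condition, so no value has a replicate error and no test across replicates was possible. The control list held 3316 peaks with a median width of 316 bp, and the NMDA list held 3646 peaks with a median width of 303 bp. Library depth is unknown. Positions are on GRCm38, and fold enrichment is the authors' value for each peak.

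The strongest peaks of each condition were described first. In control neurons they lay inside Top2b, and in NMDA-treated neurons chaperone genes were among the strongest sites. Whether the Top2b peaks come from the chromosome was not tested, as exon positions were not used here. Of the 182 NMDA peaks of at least 4-fold enrichment, 9 lay at chaperone gene ends and 11 inside Top2b, and the others lay elsewhere. The highest control peak, at chromosome 14, 16413491 to 16413843 inside Top2b, had 12.4-fold enrichment. Peaks inside Top2b took 8 of the 10 highest places in the control list. The other 2 were a 10.2-fold peak inside Prkdc (chromosome 16, 15648634 to 15649048), which encodes the catalytic subunit of DNA-dependent protein kinase, and a 4.93-fold peak at chromosome 2, 174858494 to 174858887. The second of these overlapped the third highest NMDA peak, which had 16.4-fold enrichment. The highest NMDA peak had 24.3-fold enrichment and lay inside Cep57l1 at chromosome 10, 41746125 to 41747031. The next had 19.5-fold enrichment at chromosome 12, 16836109 to 16836961, with no protein-coding gene end within 5000 bp. The following places were taken by Hspa8 (15.4-fold), Hsph1 (15.3-fold), St13 (14.8-fold), the pair Hspd1 and Hspe1 (13.98-fold), Acot7 (13.01-fold), a site inside Slc35f1 at chromosome 10, 52982737 to 52983224 (11.5-fold), and a site inside Top2b (11.5-fold).

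Peaks of high fold were few in the control list. A fold of at least 4 was listed for 17 control peaks, of which 10 lay inside Top2b, and for 182 NMDA peaks. The median fold was 2.67 in the control list and 2.69 in the NMDA list, which are scaled separately. A q below 0.05 was listed for 2286 control peaks (68.9%) and 2782 NMDA peaks (76.3%).

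**Figure D1:**
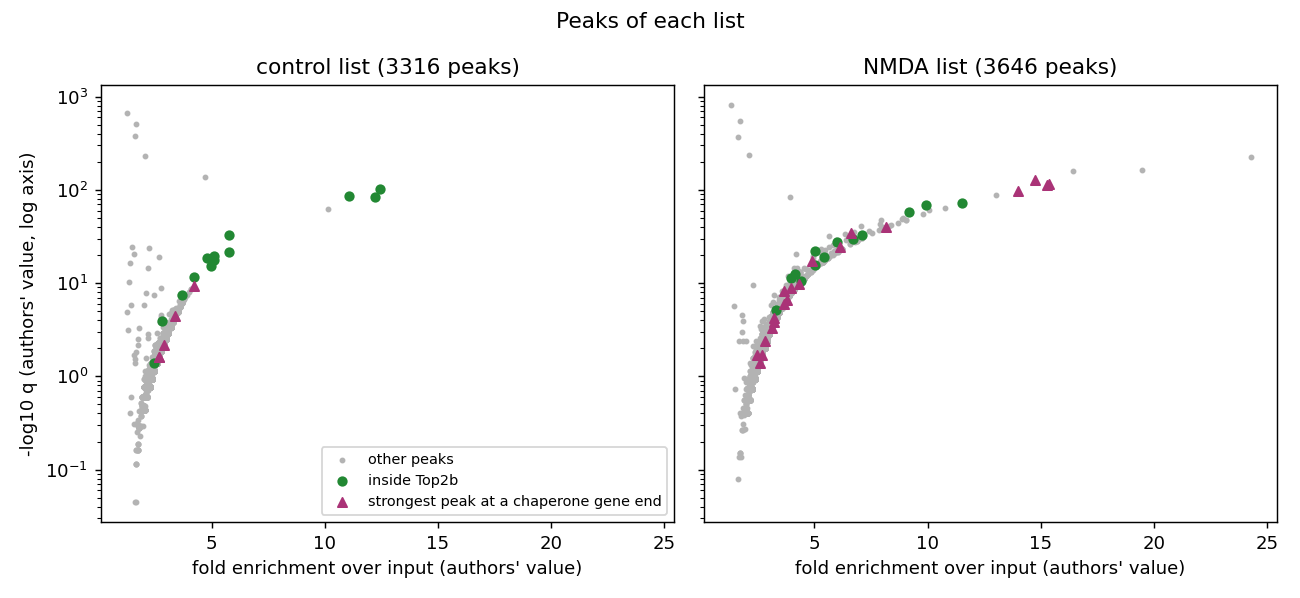
Fold enrichment of each peak (x axis, labelled as over input) against −log10 q (y axis, log scale). Both are as the authors give them, in the control list (left) and the NMDA list (right). Green circles are peaks inside Top2b and purple triangles are the strongest peaks at chaperone gene ends, which reach 4.21-fold in the control list and 15.4-fold in the NMDA list.

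The comparison of the lists addressed how many peaks were common to both conditions. Besides the peaks inside Top2b, whose origin was not tested, gene-end sites found in both lists included Hsph1, Hspd1 and Hspe1, Cct3, Dnajb1 and Smc3. Smc3 encodes a cohesin subunit. A site inside Hsf1, 5112 bp from its nearer end in the control list, was shared as well. Shared peaks were a small part of either list. Of the control peaks 96 (2.90%, 95% interval 2.35 to 3.52%) overlapped an NMDA peak, and of the NMDA peaks 95 (2.61%, 2.11 to 3.18%) overlapped a control peak. Random placement gave a mean of 5.32 and 5.35 overlaps, so the observed numbers were 18.0 and 17.8 times chance (permutation p = 0.001 for each, the smallest that the placements can give). These means include the mitochondrial peaks, which stayed in place. Without X, Y, M and unplaced sequences the means were 3.23 and 3.37, and the 94 and 93 shared peaks were 29.1 and 27.6 times chance. With gene-end peaks placed at gene ends and other peaks away from them, the observed numbers were 14.1 times chance in both lists. Without the peaks inside Top2b they were 15.9 and 15.8 times chance. Placements did not avoid assembly gaps in any setting. The shared peaks also include low-fold sites, such as a 1.27-fold control peak at chromosome 2, 98666505 to 98667515. These multiples therefore do not measure shared HSF1 binding alone. Among peaks of at least 4-fold, 14 of 17 control peaks and 17 of 182 NMDA peaks were shared. Outside Top2b these were 4 of 7 and 8 of 171.

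Shared peaks had a higher median fold than unshared peaks in both lists. The medians were 2.77 against 2.66 in the control list (permutation p = 0.00829) and 2.81 against 2.69 in the NMDA list (permutation p = 0.00771). Without the peaks inside Top2b, a setting chosen after the data were examined, the difference was 0.0235 (permutation p = 0.459) in the control list and 0.108 (permutation p = 0.277) in the NMDA list. Neither passed the threshold.

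Unshared NMDA peaks of high fold included, besides Hspa8, St13, Acot7 and the sites inside Cep57l1 and Slc35f1, a site inside Ksr2 at chromosome 5, 117607467 to 117608179 (10.8-fold), and a site inside Pla2g5 at chromosome 4, 138852905 to 138853452 (9.79-fold). Others lay at chromosome 14, 58484661 to 58485347 (10.1-fold), and chromosome 8, 119798530 to 119799295 (9.16-fold). Unshared control peaks were weaker after Prkdc. They included gene-end peaks at Dock4 (4.11-fold), Ttc21a (3.90-fold), Marchf8 (3.78-fold) and Spsb4 (3.72-fold). Sites away from gene ends lay inside Zfp608 at chromosome 18, 54986027 to 54986473 (3.80-fold), inside Atp2b1 at chromosome 10, 98947677 to 98947908 (3.70-fold), and inside Boc at chromosome 16, 44494143 to 44494375 (3.70-fold). The remaining ones lay at chromosome 7, 99249481 to 99249872 (4.00-fold), and chromosome 1, 64978622 to 64978819 (3.82-fold).

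The position of HSF1 peaks relative to genes was compared next. Peaks lay at gene ends more often than random placement gave, in both lists, and more often in the control list. In the control list 490 of 3312 placed peaks (14.8%, 95% interval 13.6 to 16.1%) lay within 1000 bp of the end of a protein-coding gene, against 3.01% by random placement. In the NMDA list these were 366 of 3644 (10.0%, 9.09 to 11.1%), also against 3.01% (permutation p = 0.001 for each list). Among unshared peaks the share was 14.3% in the control list and 9.46% in the NMDA list, an odds ratio of 1.60 (Fisher's exact test, p = 6.7e-10). Of the 182 NMDA peaks of at least 4-fold, 23 lay at gene ends, 83 inside genes away from their ends and 76 between genes.

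Chaperone genes, the best known targets of HSF1, carried gene-end peaks in both lists. In the NMDA list 21 of 43 genes (48.8%, 95% interval 33.3 to 64.5%) had a gene-end peak, against 1.84% of other protein-coding genes (odds ratio 50.9, Fisher's exact test, adjusted p = 9.7e-24). In the control list 6 of 43 had a gene-end peak (13.95%, 5.30 to 27.9%), against 2.53% of other genes (odds ratio 6.26, Fisher's exact test, adjusted p = 0.00401). The control call rests on 5 peaks, because Hspd1 and Hspe1 share 1, and it was lost with a window of 5000 bp (Fisher's exact test, adjusted p = 0.0757). All 6 control genes were among the 21 of the NMDA list, and 15 genes had a peak in the NMDA list alone (exact McNemar test, p = 6.1e-05). Within 10000 bp of the gene, but not at a gene end, Dnajb4, Cct2 and Cct4 had peaks in the NMDA list. The remaining genes of the 43 had no peak in either list within that distance, among them Hspa1a, Hspa1b, Hspb1, Cryab and Bag3. Whether reads could be placed uniquely at these genes was not examined, so a missing peak does not show that HSF1 is absent.

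The genes with a gene-end peak in both lists were Hsph1, which encodes a nucleotide exchange factor of HSP70, with 3.39-fold in the control list and 15.3-fold in the NMDA list, and Hspd1 and Hspe1, which encode the mitochondrial chaperonin, with 4.21-fold and 13.98-fold at 1 shared site (chromosome 1, 55087639 to 55088459 in the NMDA list). Ubb, a polyubiquitin gene, had 2.67-fold and 3.68-fold at peaks that do not overlap (62550068 to 62550330 and 62551091 to 62551474 on chromosome 11). The chaperonin gene Cct3 had 2.67-fold and 3.23-fold, and Dnajb1, an HSP40 gene, had 2.88-fold and 2.69-fold. In the NMDA list alone, Hspa8, which encodes constitutive HSC70, carried a peak at chromosome 9, 40800968 to 40801513. Its summit was 68 bp from the gene end. Hsp90aa1 had 8.17-fold, Dnaja1 6.63-fold, Fkbp4 6.15-fold, Chordc1 4.87-fold and Tcp1 4.30-fold. Lower values were those of Stip1 (3.98-fold), Hsp90ab1 (3.76-fold) and Ptges3 (3.66-fold). Hsf1 had 2.80-fold. The 21 chaperone gene-end peaks of the NMDA list had a median fold of 3.76, above the median of that list (permutation p = 1e-05, the smallest that the resamples can give). The 5 of the control list had a median of 2.88 against 2.67 for that list, which did not pass (permutation p = 0.336).

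**Figure D2:**
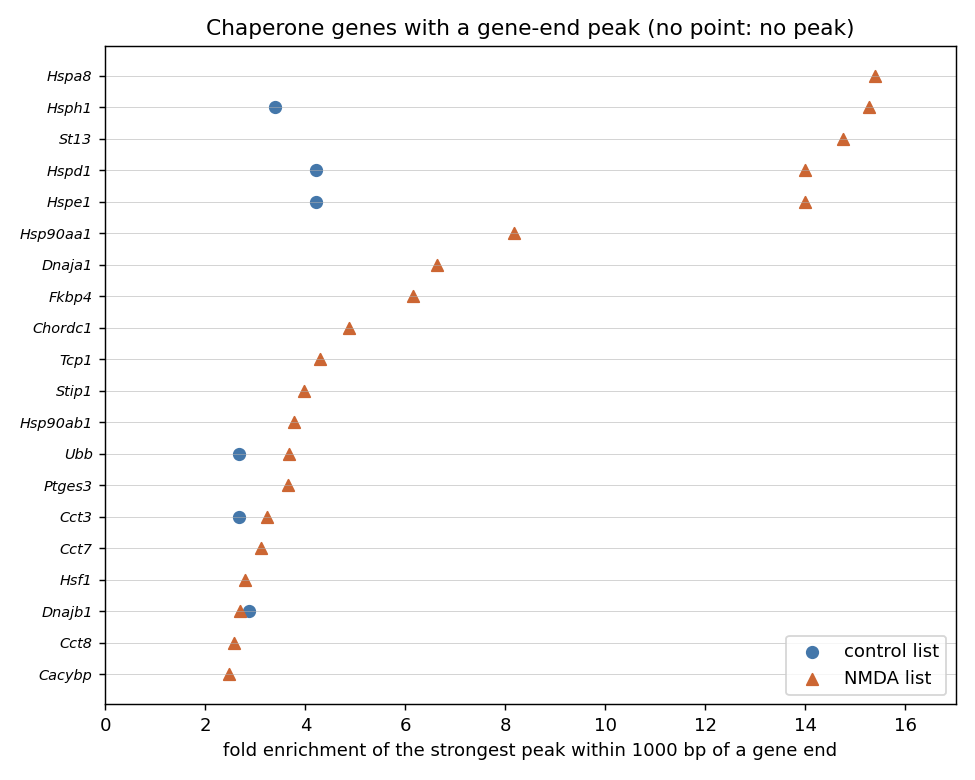
Fold enrichment (x axis) of the strongest peak within 1000 bp of a gene end for 20 of the 21 chaperone genes with such a peak, in the control list (circles) and the NMDA list (triangles). Circles are present for 6 genes, and the highest triangles are Hspa8 (15.4-fold) and Hsph1 (15.3-fold).

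Immediate early genes, which neurons transcribe within minutes of activity, did not pass the test in either list. In the control list 2 of 37 had a gene-end peak, Ccn1 (3.08-fold) and Homer1 (2.83-fold), with an adjusted p of 0.594 by Fisher's exact test. In the NMDA list 1 of 37 had one, Egr1 (3.01-fold), with an adjusted p of 1. With a window of 5000 bp the counts were 6 of 37 in the control list (odds ratio 3.63) and 5 of 37 in the NMDA list (odds ratio 3.99), and neither passed (Fisher's exact test, adjusted p = 0.0541 for each).

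Of the other gene groups, olfactory receptor genes, used mainly by olfactory sensory neurons, had no gene-end peak among 1110 genes in either list (up to 0.332% by the exact interval). They lay below other genes by Fisher's exact test (adjusted p = 2.9e-12 in the control list and 2.7e-09 in the NMDA list). No other group passed. Topoisomerase, break repair and cohesin genes had 2 of 24 in each list, Top2b and Smc3 (Fisher's exact test, adjusted p = 0.454 and 0.342). Synaptic genes had 1 of 33 in each list, Homer2 in the control list and Gad1 in the NMDA list. Proteasome genes had 2 of 31 in the control list, Psmd1 and Psmd11, and 0 in the NMDA list. Ribosomal protein genes had 1 of 81 in each list, Rpl23a and Rps27. Of the astrocyte markers Slc1a2 had a gene-end peak in the NMDA list, and the markers of neurons, microglia and the oligodendrocyte lineage had 0 in both lists.

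Top2b itself (chromosome 14, 16365206 to 16430787) held 13 peaks in each list. Of the control peaks 11 overlapped an NMDA peak. The median fold of its peaks was 5.10 in the control list and 5.42 in the NMDA list. The site with the highest NMDA value, at 16409744 to 16410068 in that list, had 12.2-fold in the control list and 11.5-fold in the NMDA list. The difference between the lists was not tested, because each has its own scale.

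**Figure D3:**
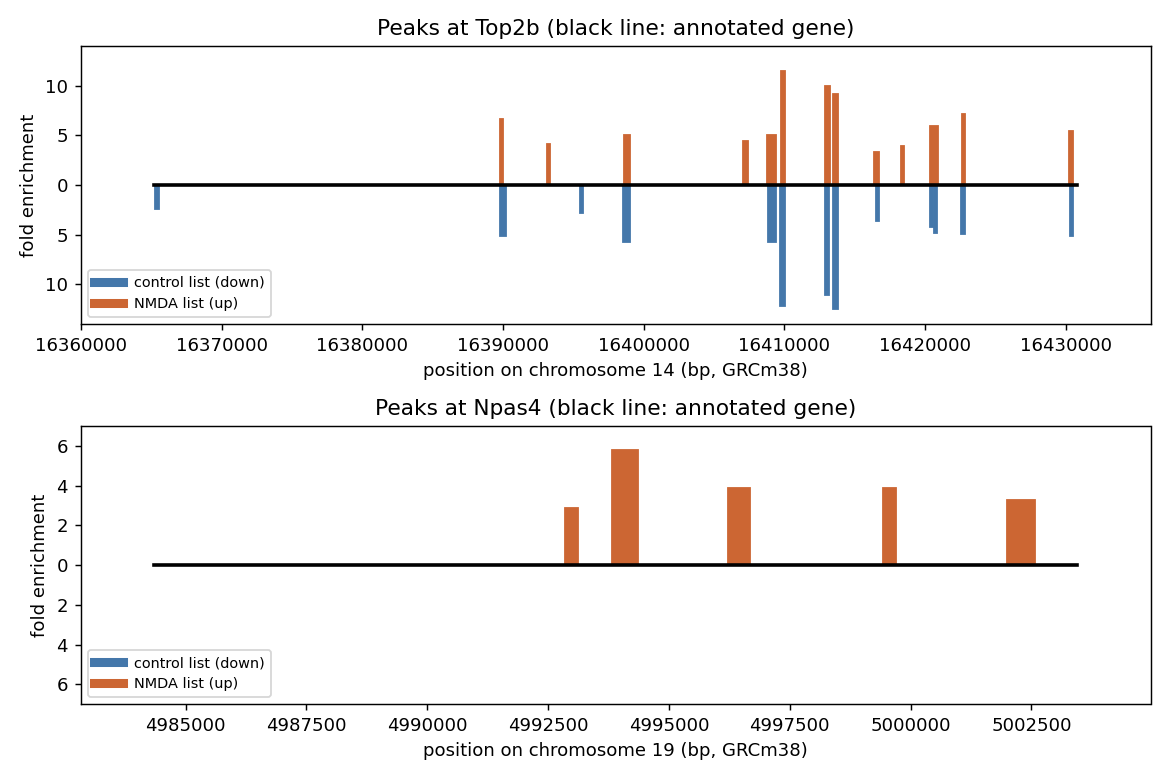
Peaks at Top2b and Npas4 drawn to scale along the chromosome (x axis, bp), with bar height the fold enrichment in the NMDA list (upward) and the control list (downward). Top2b has 13 peaks in each list, and Npas4 has 5 in the NMDA list and 0 in the control list.

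Peaks were spread over all autosomes and were nearly absent from chromosome X. Chromosome X held 3 of 3312 control peaks and 5 of 3644 NMDA peaks, where its length gave an expectation of 216 and 238 (exact binomial test, p = 3e-91 and 1.9e-97). Autosomes held from 1.11 to 1.68 peaks per Mb in the control list and from 1.01 to 1.92 in the NMDA list. Neither list held a peak on the Y chromosome, which was not analysed further.

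**Figure D4:**
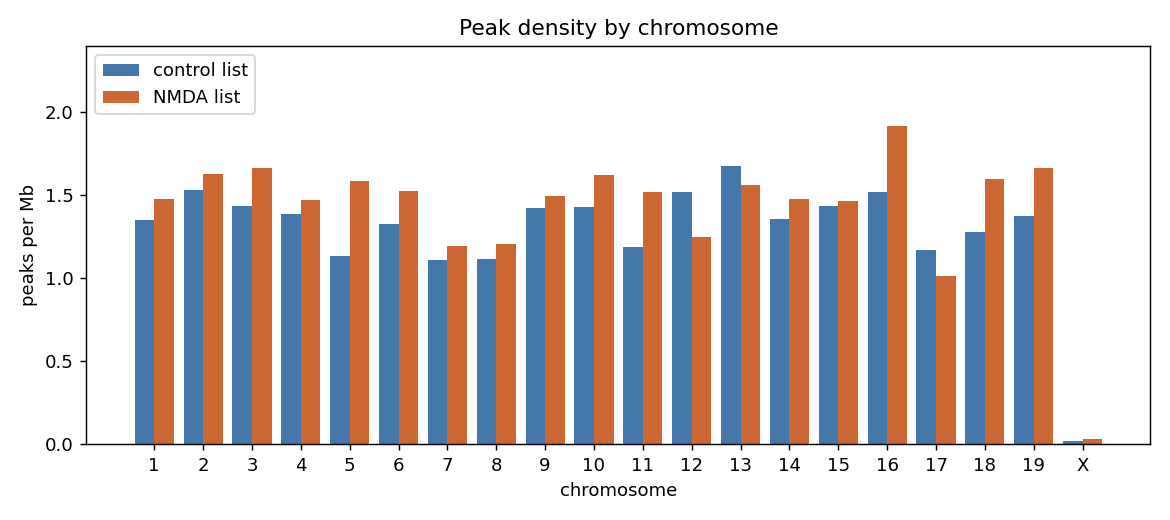
Peaks per Mb (y axis) on each chromosome (x axis) in the control list and the NMDA list. Every autosome lies above 1 peak per Mb, and chromosome X lies at 0.0176 in the control list and 0.0293 in the NMDA list.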

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

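The settings without Top2b, with peaks of at least 4-fold and with a gene body window, and those of the exact McNemar test, were chosen after the data were examined. Of 92 planned values 88 kept their direction and side of the threshold, and of 50 added ones 35 did. Many of the values that did so belong to gene lists without a call in either setting. The tally therefore says little about the called results. Overlap and gene-end shares kept their direction and side of the threshold throughout. Without the peaks inside Top2b the difference in median fold was 0.0235 in the control list and 0.108 in the NMDA list. With 5000 bp either side, chaperone genes in the control list stayed at 13.95% but lost the call, since more other genes had a peak. That window turned the direction, without a call, for ribosomal protein genes (4.94%) and neuronal markers (6.67%) in the NMDA list. Among peaks at or above the median −log10 q, proteasome genes had 0% in the control list. With only peaks of at least 4-fold enrichment, 0% of immediate early, synaptic, proteasome and olfactory receptor genes had a control peak, and 0% of immediate early, synaptic, astrocyte and olfactory receptor genes had an NMDA peak. Olfactory receptor genes lost both calls there, where few genes have a peak. With the gene body or 10000 bp around it, chaperone genes in the control list lost the call at 16.3% against all other genes (but passed against genes of like length, adjusted permutation p = 0.0381), synaptic genes gained it at 39.4% in the control list and 42.4% in the NMDA list, and neuronal markers turned, without a call, at 13.3% and 26.7%. The cause was not tested except where stated. Heat shock element and repeat alternatives were not run, as genome sequence was not used here. Leaving out each replicate was not run, because each list combines both libraries. No paired analysis was possible because the lists hold no values per replicate. Depth is unknown and its effect on these counts was not tested.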

Other observations

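The tests of this part were chosen after the results were seen. Only for gene length at synaptic genes was the rule for reading the outcome written before the test result. Its window around the gene body was still chosen after the data were examined. Npas4, an activity-induced transcription factor gene (chromosome 19, 4984353 to 5003439), held 5 peaks in the NMDA list and 0 in the control list. At 26.2 peaks per 100 kb it had the highest density of the genes with at least 3 peaks in that list. Its strongest peak, at 4993814 to 4994370, had 5.81-fold enrichment. An 8.87-fold NMDA peak lay 5729 bp from the nearer end of Egr1, at chromosome 18, 34855142 to 34855786, with no control peak there. Fosb held 1 NMDA peak (3.01-fold). Other immediate early genes went the other way. Within 10000 bp of the gene, Rgs2, Nr4a2, Ccn1, Per1 and Dusp1 had a peak in the control list only. Npas4, Egr1, Fosb and Rheb had peaks in the NMDA list only. With a window of 10000 bp around the gene body, 6 of 37 immediate early genes had an NMDA peak, against 9.40% of other genes (Fisher's exact test, p = 0.155). Immediate early genes are short, with a median length of 5.30 kb. Against random genes of like length, which had a mean of 1.78, the 6 genes gave an adjusted permutation p of 0.0142 over 6 such tests (one-sided). The control list gave 7 genes and the same adjusted p. In the same tests chaperone genes had 7 of 43 in the control list against a matched mean of 2.95 (adjusted permutation p = 0.0381) and 24 of 43 in the NMDA list against 2.67 (adjusted permutation p = 0.0006, the unadjusted 0.0001 being the smallest these sets can give). Immediate early genes may therefore lie near peaks of both lists more often than their length accounts for, and the matched test shows no excess particular to NMDA. Genes were matched on length alone, so crowding of neighbouring genes stays open.

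Synaptic genes had few gene-end peaks but many peaks in or near the gene body, counted within 10000 bp of the gene. Dlg2 had 4 control and 11 NMDA peaks, Nrxn3 had 6 and 1, and Nlgn1 had 6 and 4. A peak was found at 13 of 33 genes in the control list and 14 of 33 in the NMDA list. Random genes of like length gave a mean of 9.48 and 9.92 (one-sided permutation p = 0.0941 and 0.0647). Length is consistent with these counts, although a modest excess is not excluded.

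The 15 chaperone genes with a peak in the NMDA list alone could come from a list with more gene-end peaks. That is argued against, because other genes had 491 in the control list alone and 343 in the NMDA list alone (Fisher's exact test, p = 1.99e-06). Lower enrichment in the control libraries stays open. The control list had 7 peaks of at least 4-fold outside Top2b and the NMDA list 171. Inside Top2b the lists had 10 and 11, with medians of 5.10 and 5.42, which goes the other way, but the origin of those peaks is open too. Fold is scaled separately in each list, which limits both comparisons. No list per replicate or site known to be left alone by NMDA was used here. A rise of HSF1 binding at chaperone genes with NMDA and lower enrichment in the control libraries cannot be told apart.

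The 13 peaks inside Top2b could come from extra copies of the region in the genome, which would raise the input too. Cwc22, a gene of varying copy number in mice, had 9 control peaks of at most 2.68-fold and 4 NMDA peaks of at most 2.28-fold. The Top2b medians of 5.10 and 5.42 exceed both, but copy number was not measured here for either gene, so extra copies stay open. Top2b DNA from outside the chromosome, such as a plasmid or cDNA, is a candidate explanation that stays open as well: 11 control peaks overlapped an NMDA peak, and exon positions that would test it were not used here. No biological explanation was tested.

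Complete removal of chromosome X by a filter is argued against by the 3 control peaks and 5 NMDA peaks that lie there. Gene content is argued against as well: chromosome 12 has the same gene density to 3 digits (5.66 protein-coding genes per Mb) and 18.3 times the upper limit of the X peak density in the NMDA list. A first form of that test asked whether X lay within the range of the autosomes, which it missed by a margin below these digits, and it was replaced after that outcome was seen. Fewer copies of X in the culture stays open: among NMDA peaks of at least 4-fold, 0 lay on X where 11.9 were expected, and the upper limit of the ratio was 0.307, while weaker peaks had a ratio of 0.0221. No biological explanation was tested.

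The strongest peak p-values belonged to peaks of low fold. The peak at chromosome 2, 98666505 to 98667515, had 1.27-fold enrichment and a −log10 p of 676 in the control list. The mitochondrial genome held 2 peaks in each list, of 1.59-fold to 1.72-fold.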
